A study of Homo sapiens with 6 samples.

How the data were processed

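Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody to β-catenin in SA121 cells, a human embryonic stem cell line, 6 h after a change of medium. The series has 6 samples: 3 with the β-catenin antibody and 3 with control goat IgG, 1 of each per condition. The conditions were RPMI medium without inhibitor, RPMI with CHIR99021 (CHIR), and RPMI with CHIR and SB431542 (CHIR+SB). CHIR inhibits the kinase GSK3, which marks β-catenin for degradation, so CHIR stabilises β-catenin. SB431542 inhibits the type I receptors for activin, Nodal and TGFβ. Per the labels' protocols, DNA from several parallel ChIPs was pooled before each library was made, so the parallel ChIPs cannot be compared with each other. Doses are not given here because the unit in the labels could not be checked.

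Per the submitters' processing notes, reads were aligned with Bowtie and the builds hg19 and mm9 were named. The gene positions in the human peak lists are those of hg19, and coordinates are printed as the lists give them. The peak caller, its thresholds, the Bowtie version and the total depth of each library are not given in the sources used here. The authors deposited 1 peak list for each β-catenin library. Per the file headers, each peak has a position, the counts of reads in the β-catenin library and in the IgG library, both counts in normalized form, their ratio and −log10 p-values. The lists also give the gene the authors assigned to the peak and the distance from the peak to its transcription start site (TSS). The deposited counts are whole reads within the boundaries of the peak in that list. The deposited normalized signal was the count multiplied by 1 factor per library, the same for every peak of a list. The deposited ratio of β-catenin to IgG signal holds the placeholder 10000 where the IgG count is 0, and medians were taken with it. The lists write decimal commas, which were read as points. Relative depth was taken as the inverse of the factors, which assumes that the authors scaled the libraries to a common depth. The IgG samples were used only through the counts beside each peak, and their peaks were not analysed here.

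The score used for ranking was the normalized β-catenin signal, chosen after the columns were seen. Within a list it gives the same order as the read count. Peaks of 2 lists were called overlapping when they shared at least 1 bp. Chance overlap came from 1000 random placements of one list, with the peak widths and chromosomes kept, inside the span covered by any of the lists. Placement was uniform and took no account of open chromatin or of where reads can be aligned. A promoter peak had its centre within 1 kb of the TSS of the assigned gene. Shares carry exact 95% binomial (Clopper-Pearson) intervals.

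Before the data were examined, 10 gene lists with 258 genes in all were fixed. They held Wnt pathway genes and targets, primitive streak genes, Nodal/SMAD2/3 genes, pluripotency genes, BMP targets, neurectoderm genes, trophoblast genes, HOX genes, genes of differentiated cells and housekeeping genes. A member counted as near a peak when the authors assigned a peak within 50 kb of its TSS to it. Each list was compared with all 20056 protein-coding genes of the reference table (assembly GRCh38.p14, used for names only) by a one-sided Fisher exact test. Benjamini-Hochberg adjustment covered the 10 lists within a peak list. Percentiles among random gene lists matched on the distance between neighbouring TSSs had been planned. They were not run because no genome or annotation in hg19 was used here, and the Fisher test stated in the plan for that case took their place. The Fisher test does not correct for the long intergenic stretches around developmental genes. To set lists against each other, 5 of them were compared with the neurectoderm list by a two-sided Fisher exact test in the CHIR and CHIR+SB lists, 10 tests in all. This comparison of lists was chosen after the data were seen. Of the gene names in the lists, 100% matched the reference table in RPMI, 99.2% in CHIR and 99.4% in CHIR+SB. TBXT, CRIPTO and LINC01124 are the current symbols of genes for which the lists use older ones.

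Signal was compared between lists at peaks that overlapped one-to-one, so that neither peak met a second peak of the other list. This rule was set after it was seen that some wide peaks spanned several peaks of the other list. Each ratio of normalized signals has an exact 95% interval from the read counts of both libraries. Medians over pairs have 95% bootstrap intervals from 10000 draws. Each count covers the boundaries of its own list, and only peaks called in both lists enter. A motif analysis and a genomic background for peak positions had been planned and were not run, since both need the hg19 sequence or annotation.

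Each condition had 1 β-catenin library, so there was no spread between replicates, and no p-value is given for a difference between conditions. Tests over genes or peaks describe these lists. Intervals and tests on reads cover counting error only and compare libraries, not conditions. The genes named in the text were fixed by rule. They were members of the Wnt, primitive streak, Nodal and pluripotency lists with a peak within 50 kb in CHIR or CHIR+SB, at most the 30 with the highest signal. To these were added the genes of the 10 highest peaks in each list, leaving out symbols that begin with LOC or LINC and accessions, and the list members near a peak in only one of the CHIR and CHIR+SB lists. Not every gene that met the rule is named. Any other gene named was chosen after its values were seen.

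Alternatives covered stricter minima for the signal, other overlap rules, other windows and promoter distances, lists of equal length and lists without the peaks found in RPMI. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data, all 400 overlaps planted in a list of 1053 peaks were recovered, and 1% of 100 random placements reached p under 0.05. Of random gene lists drawn from the 20056 genes, 4.5% reached p under 0.05 in the CHIR list, against 100% of lists with 5 added genes near CHIR peaks. The exact interval held the true ratio in 96.55% of 2000 simulated ratios between the CHIR and CHIR+SB libraries.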

Results

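β-catenin, the transcriptional effector of Wnt signalling, was mapped by ChIP-seq in SA121 human embryonic stem cells after 6 h in RPMI, CHIR or CHIR+SB. The series asks where β-catenin binds when Wnt signalling is activated, and how that binding differs when activin/Nodal signalling is blocked at the same time. There was 1 β-catenin library per condition and no replicate. The lists hold 6272 reads within peaks in RPMI, 39408 in CHIR and 39022 in CHIR+SB, over 82.6, 398.7 and 559.1 kb of sequence. The IgG libraries had 1294, 4362 and 12664 reads in the same peaks. By the authors' scaling factors, the depth of the β-catenin library relative to RPMI was 1.67 in CHIR and 1.14 in CHIR+SB. The depth of the IgG library relative to RPMI was 0.976 in CHIR and 1.75 in CHIR+SB.

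The first comparison is between cells in RPMI and cells with CHIR. AXIN2, the negative feedback regulator of Wnt signalling, had no peak in RPMI and 7 peaks in CHIR. CDX2, a transcription factor of trophoblast and posterior embryo, had the third highest peak of the CHIR list and none within 50 kb in RPMI. The Wnt-induced transcription factor SP5 and the primitive streak genes EVX1, MIXL1 and EOMES also had peaks in CHIR and none within 50 kb in RPMI. The lists held 260 peaks in RPMI and 1053 in CHIR, 4.05 times as many. With the highest of the 3 lists' minimum signals, 9.61, applied to each list, a limit chosen after the data were seen, 260 and 741 peaks remained, a ratio of 2.85. The depth and the lowest signal differed between the libraries, and the difference in peak number has no replicate check.

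The 10 highest peaks in RPMI lay at promoters. The RBM39 promoter, of an RNA-binding splicing factor, ranked first in all 3 lists, with 115 reads and 15 IgG reads in RPMI (chromosome 20, 34329882 to 34330714). CDK12 and ERCC6L2 ranked among the 10 highest peaks in each list. The CDK12 peak had 85 reads in RPMI and the ERCC6L2 peak 83. PRDX1, RNF167 and CDC5L were in the top 10 in RPMI, as were ASXL1, RPL10A and QRICH1. Among all peaks, 55.0% in RPMI were at promoters (143 of 260, 95% interval 48.7 to 61.2%), against 26.6% in CHIR (280 of 1053, 23.9 to 29.4%). The median distance to the TSS was 295 bp in RPMI and 15578 bp in CHIR. Of the CHIR peaks that overlapped an RPMI peak, 74.3% were at promoters (133 of 179, 67.2 to 80.5%), and of those that did not, 16.8% were (147 of 874, 14.4 to 19.5%).

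Most RPMI peaks were found again with the inhibitors. Of the 260 RPMI peaks, 181 overlapped a CHIR peak (69.6%, 63.6 to 75.1%), 160 a CHIR+SB peak (61.5%, 55.3 to 67.5%) and 154 both. In a permutation test by random placement, at most 2 peaks overlapped for either list (p = 0.001, the smallest that 1000 placements can give). The placement took no account of open chromatin, so the test says only that the overlap exceeded uniform placement. In 4 equal groups by signal, from lowest to highest, 30.8%, 58.5%, 90.8% and 98.5% of RPMI peaks overlapped a CHIR peak. With the 260 highest peaks taken from each list, 44.6% of RPMI peaks overlapped a CHIR peak and 36.2% a CHIR+SB peak. At 174 peaks that overlapped one-to-one, CHIR signal was a median of 1.23 times RPMI signal (95% interval 1.12 to 1.30), and at 130 promoter peaks 1.21 times (1.102 to 1.29). The CHIR peaks were a median of 1.36 times as wide as their RPMI partners, which adds reads to them.

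**Figure D1:**
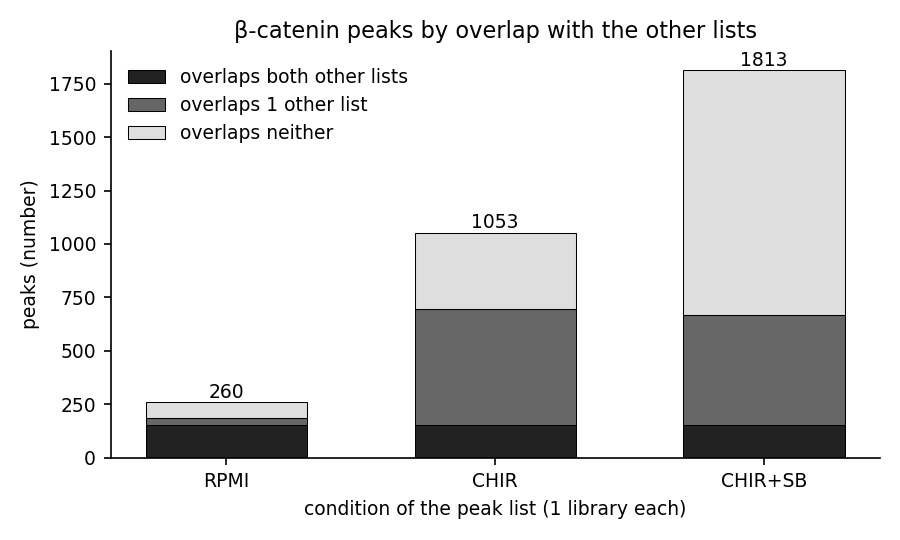
Number of β-catenin peaks (vertical axis) in each condition's list, 1 library each, split by whether the peak overlaps peaks of both other lists, of 1 other list or of neither by at least 1 bp. Bars hold 260, 1053 and 1813 peaks, of which 154 in RPMI overlapped both other lists and 1143 in CHIR+SB overlapped neither.

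Genes of the Wnt pathway and of the primitive streak, the site where mesoderm and endoderm form, were near CHIR peaks more often than protein-coding genes as a whole. Of 37 Wnt genes, 16 had a CHIR peak within 50 kb, and of 39 primitive streak genes, 17 did, against 539 of 20056 protein-coding genes (2.69%). The odds ratios were 28.4 (one-sided Fisher exact test, adjusted p = 2.27e-15) and 28.9 (adjusted p = 4.58e-16). The lists share 5 members, CDX1, CDX2, SP5, WNT3 and WNT8A, and without these 11 of 32 and 12 of 34 genes were near a CHIR peak. In RPMI, WNT8A was the 1 member of either list near a peak, and no list passed the test there.

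Among the Wnt genes, the CHIR peak with the highest signal for CDX2 lay 3.08 kb from the TSS within the gene (chromosome 13, 28539820 to 28541028), with 177 reads and 12 IgG reads. The SP5 peak lay 0.205 kb from the TSS (chromosome 2, 171571295 to 171572007), with 85 reads and 7 IgG reads. CCND1, which encodes the cell cycle protein cyclin D1, had a promoter peak of 33 reads. TCF7, a DNA-binding partner of β-catenin, had a peak of 45 reads at 43.4 kb. The Wnt receptor gene FZD7 had 4 CHIR peaks within 50 kb. MYC had 1 peak of 31 reads at 7.002 kb. CDX1 had a promoter peak of 74 reads, and AMOTL2 one of 45 reads. WNT3 had 2 peaks, SP8 had 1, and MSX1 had 1 peak of 60 reads upstream of the gene.

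At AXIN2, the CHIR list had 4 peaks within 1.22 kb of the TSS, with 26, 61, 67 and 32 reads. Further peaks lay 11.4 and 32.2 kb upstream, with 32 and 72 reads, and 66.4 kb from the TSS beyond the end of the gene, with 40 reads. The CHIR+SB list had 1 peak of 81 reads over the TSS (chromosome 17, 63556640 to 63558080). It had peaks at the same upstream and downstream positions, with 34, 60 and 29 reads, and 1 more, of 32 reads, 45.4 kb from the TSS. At these shared positions the normalized signal in CHIR+SB was 1.56 (0.932 to 2.61), 1.22 (0.852 to 1.74) and 1.06 (0.635 to 1.76) times that in CHIR. The CHIR+SB peaks there were 1.75, 1.30 and 1.28 times as wide. No ratio was taken over the TSS, because the CHIR+SB peak at the TSS overlapped several CHIR peaks. Its signal was 45.6, against 23.4, 25.7 and 12.3 in those CHIR peaks, which together exceed it.

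**Figure D2:**
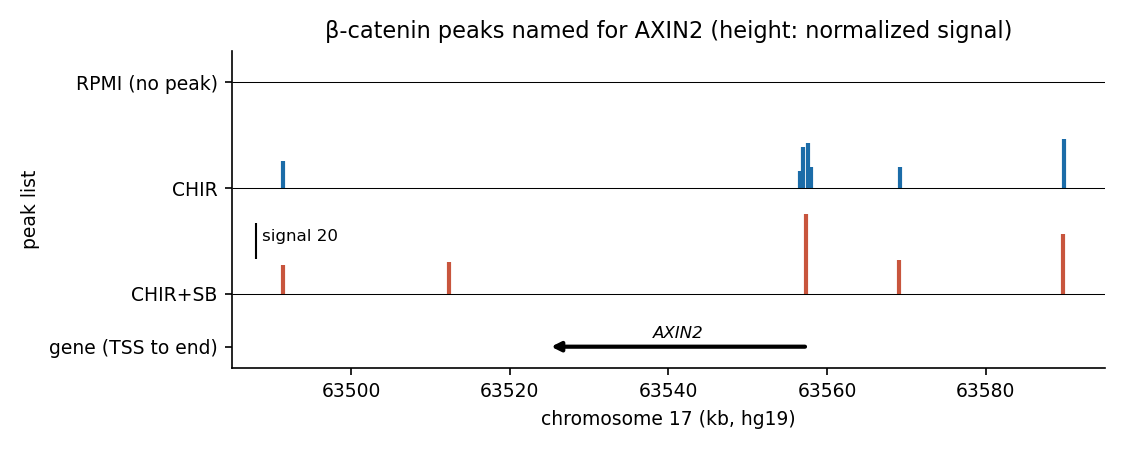
Map of chromosome 17 around AXIN2 (kb, hg19, horizontal axis) with 1 track per peak list. Bars mark the centres of peaks the authors assigned to AXIN2, their height is the normalized signal (scale bar, 20), and the arrow runs from the TSS to the end of the gene. There are 7 peaks in CHIR, 5 in CHIR+SB and none in RPMI.

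Among the primitive streak genes, EVX1 had 4 CHIR peaks, the highest with 98 reads 2.85 kb upstream (chromosome 7, 27278947 to 27279671). EOMES, a T-box factor of mesendoderm, had a peak of 78 reads at 6.31 kb (chromosome 3, 27769664 to 27770519). MIXL1 had 75 reads at 12.9 kb, GATA4 69 reads at 5.84 kb and NODAL 62 reads at 13.8 kb. The growth factor genes FGF17 and FGF8 had peaks of 51 and 45 reads. TBXT, the gene for brachyury, had a peak of 28 reads and 4 IgG reads 0.757 kb from the TSS within the gene (chromosome 6, 166581261 to 166581540). WNT8A had a peak in every list about 11.5 kb from the TSS, with 27 reads in RPMI, 64 in CHIR and 48 in CHIR+SB. The normalized signal of these peaks was 17.3, 24.6 and 27.0.

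Other developmental lists were near CHIR peaks as well, in part through genes that are also in the Wnt or primitive streak lists. These were NODAL and DACT1, the BMP targets BMP4, HAND1 and MSX1, and the trophoblast genes CDX2 and HAND1. The tests below were not repeated without them. The Nodal/SMAD2/3 list had 5 of 26 members (among them NODAL, CRIPTO, FOXH1 and DACT1, one-sided Fisher exact test, adjusted p = 0.00081). The pluripotency list had 6 of 26, among them POU5F1, which encodes OCT4, with 68 reads 1.40 kb upstream (exact test, adjusted p = 0.000107). By the same exact test, BMP targets had 6 of 17 (adjusted p = 1.17e-05), HOX genes 8 of 39 (adjusted p = 1.91e-05), neurectoderm genes 6 of 27 (adjusted p = 0.000112) and trophoblast genes 3 of 15 (adjusted p = 0.00863). Of 28 genes of differentiated cells 1 was near a peak, SERPINA1 (exact test, adjusted p = 0.593), and of 24 housekeeping genes none was. With the 260 highest peaks of the CHIR list, Wnt and primitive streak genes passed the test and no other list did. Above the median signal of the CHIR list, neurectoderm (exact test, adjusted p = 0.0948) and trophoblast genes (adjusted p = 0.264) did not pass either. The share of members near a CHIR peak was 43.2% for Wnt genes and 22.2% for neurectoderm genes, and a direct two-sided Fisher exact test did not separate these lists (odds ratio 2.67, p = 0.111, adjusted p = 0.381). Above the median signal of the CHIR list, 13 of 37 Wnt genes and 2 of 27 neurectoderm genes were near a peak (odds ratio 6.77, Fisher exact test, p = 0.0153, adjusted p = 0.105).

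**Figure D3:**
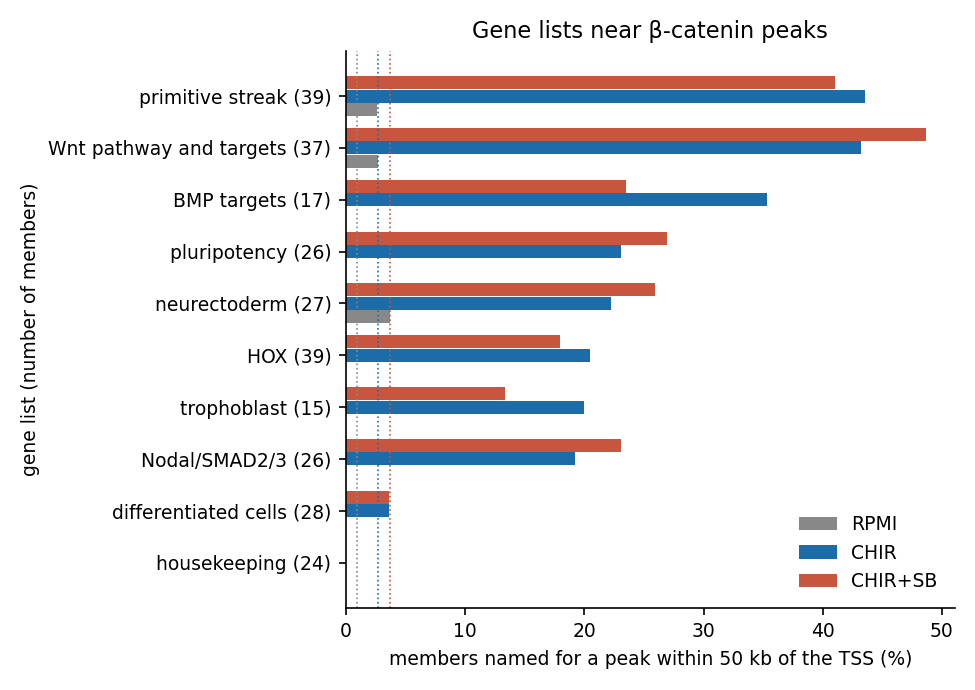
Percent of the members of each gene list (horizontal axis) that the authors assigned to a β-catenin peak within 50 kb of the TSS, for the 3 peak lists, with the number of members in brackets on the vertical axis. Dotted lines give the percent among all protein-coding genes, 0.888% in RPMI, 2.69% in CHIR and 3.73% in CHIR+SB. Wnt and primitive streak genes reach 43.2 and 43.6% in CHIR, and housekeeping genes have no bar.

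The second comparison asks what changed when activin/Nodal receptors were blocked along with CHIR. Wnt and primitive streak genes were near peaks with both treatments. AXIN2, SP5, CDX2 and EVX1 were among the 10 highest peaks of the CHIR+SB list. LINC01124, a noncoding gene next to SP5, was also among them and was named after its value was seen. The AXIN2 and EVX1 peaks each overlapped separate peaks of the CHIR list, so their ranks do not show a higher signal in CHIR+SB. The EVX1 peak had a signal of 52.9, against 37.6 and 24.96 in the CHIR peaks it overlapped, which together exceed it. NODAL, EOMES, MIXL1, GATA4 and POU5F1 each had a peak in both lists. Of 37 Wnt genes 18 were near a CHIR+SB peak (odds ratio 24.997, one-sided Fisher exact test, adjusted p = 1.48e-15), and of 39 primitive streak genes 16 were (odds ratio 18.3, adjusted p = 1.03e-12). In both CHIR and CHIR+SB, 14 Wnt and 14 primitive streak genes were near a peak. This did not require the same site: the CHIR peak near SP8 lay 11.6 kb from the TSS upstream, and the CHIR+SB peak 10.4 kb from it downstream. The peaks near GSC did not overlap either but lay close together, 1.64 kb (CHIR) and 1.40 kb (CHIR+SB) from the TSS within the gene.

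The Nodal/SMAD2/3 list was also near peaks under receptor blockade, with 6 of 26 members (one-sided Fisher exact test, adjusted p = 0.000645), 5 of them shared with CHIR. NODAL and DACT1 also counted in the Wnt or primitive streak lists, as did the BMP target MSX1 and the trophoblast gene CDX2. Pluripotency genes (7 of 26, adjusted p = 0.000114), neurectoderm genes (7 of 27, adjusted p = 0.000114), HOX genes (7 of 39, adjusted p = 0.000889) and BMP targets (4 of 17, adjusted p = 0.00445) passed the same exact test. Trophoblast genes (2 of 15, adjusted p = 0.133) and genes of differentiated cells (1 of 28, adjusted p = 0.729) did not pass this exact test, and no housekeeping gene was near a peak. With the 260 highest peaks of the CHIR+SB list, the Nodal and BMP lists had 1 member each (exact test, adjusted p = 0.266 and 0.21) and the neurectoderm list none. At the common signal minimum, BMP targets (adjusted p = 0.0706) and neurectoderm genes (adjusted p = 0.139) did not pass the exact test, nor did BMP targets within 10 kb (adjusted p = 0.0733). Against the neurectoderm list, none of the Wnt, primitive streak, Nodal, pluripotency and HOX lists stood apart in CHIR+SB by the two-sided Fisher exact test (lowest p = 0.0761, adjusted p = 0.381, for Wnt genes).

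Near a peak in CHIR and not in CHIR+SB were 13 members of the fixed lists. They included TBXT, BMP4 and HAND1, the Wnt genes MYC and NOTUM, and the pluripotency genes DPPA4, VRTN and ZSCAN10. The others were the neurectoderm genes EMX2, LHX2 and NKX6-1 and the HOX genes HOXB1 and HOXD3. Their CHIR peaks had 20 reads (HAND1 and LHX2) to 43 reads (NKX6-1).

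Near a peak in CHIR+SB and not in CHIR were 16 members. They included the Wnt genes DKK1, RNF43, TCF7L2 and WNT5B, the pluripotency genes SOX2, LIN28A, L1TD1 and SALL1, and the neurectoderm genes EN1, NEUROG2 and SIX6. HHEX, MSGN1, HOXA10 and SMAD2 were also among them. Their peaks had 14 reads (MSGN1 and SIX6) to 22 reads (RNF43). A further 42 members were near a peak in both, though not always at the same site. For GSC, MSX2, PAX3, SP8 and TBX3 the highest peak of each list overlapped no peak of the other. The GSC peaks still lay close together, so separate sites cannot be claimed for that gene. Above the common signal minimum lay 9 of the 13 CHIR peaks and 4 of the 16 CHIR+SB peaks (L1TD1, RNF43, SALL1 and TCF7L2). The balance of 13 CHIR members to 16 CHIR+SB members turned with the setting: it was 15 to 8 within 10 kb, 15 to 8 with the common minimum applied to both lists, 4 to 3 with the 260 highest peaks of each and 4 to 16 above the median of each. Membership of one list alone rests on 1 library per condition and was not tested between conditions.

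The CHIR+SB list held 1813 peaks, 1.72 times as many as CHIR, and 262 of them were at promoters (14.5%, 12.9 to 16.2%). Of the CHIR peaks, 667 overlapped a CHIR+SB peak (63.3%, 60.4 to 66.3%), and of the CHIR+SB peaks 663 overlapped a CHIR peak (36.6%, 34.3 to 38.8%). In the permutation test by random placement at most 4 did (p = 0.001, the smallest possible). In 4 such groups, from lowest to highest signal, 4.63%, 17.7%, 38.9% and 85.2% of CHIR+SB peaks overlapped a CHIR peak. The same shares of CHIR peaks in the CHIR+SB list were 32.6%, 54.0%, 73.8% and 93.2%. The lowest signal in a peak was 7.68 in CHIR and 6.75 in CHIR+SB. At the CHIR minimum the CHIR+SB list held 1807 peaks, 1.716 times as many as CHIR. Above the common minimum of 9.61 the lists held 741 and 874 peaks, a ratio of 1.18, and 55.0% of these CHIR+SB peaks overlapped a CHIR peak. Among the 260 highest peaks of each list it was 68.8%.

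Signal at peaks present in both lists differed little on the whole. At 642 peaks that overlapped one-to-one, CHIR+SB signal was a median of 1.00 times CHIR signal (0.977 to 1.04). At CDX2, signal was lower in the CHIR+SB library (84 against 177 reads, ratio 0.695, exact 95% interval 0.530 to 0.906). It was lower too at RPL10A (0.493, 0.320 to 0.744) and at ARF3 (0.646, 0.463 to 0.891). It was higher at SP5 (85 reads in each library, ratio 1.46, 1.07 to 2.003) and at JARID2 (1.87, 1.21 to 2.90), a pluripotency list gene with a peak 37.4 kb upstream. The boundaries moved the same way as the signal at these 5 peaks. The CHIR+SB peak was 0.768 times as wide as the CHIR peak at CDX2 (928 against 1208 bp), 0.674 times at RPL10A and 0.872 times at ARF3. It was 1.38 times as wide at SP5 (984 against 712 bp) and 1.64 times at JARID2, so part of each ratio may come from the width counted. IgG reads were 7 in CHIR and 27 in CHIR+SB at SP5. Signal over IgG there was 6.61 in CHIR (exact 95% interval 3.07 to 16.9) and 4.50 in CHIR+SB (2.89 to 7.22). These intervals overlap, so signal over IgG did not show the higher value in CHIR+SB that the signal itself showed. At CDX2 there were 12 and 32 IgG reads, and signal over IgG was 8.03 (4.48 to 15.8) in CHIR and 3.75 (2.47 to 5.83) in CHIR+SB. For MIXL1 the ratio was 1.17 (0.820 to 1.67), for NODAL 1.21 (0.815 to 1.77), for EOMES 1.01 (0.703 to 1.45), for GATA4 0.998 (0.674 to 1.47) and for POU5F1 0.862 (0.568 to 1.29). At 24 such peaks within 50 kb of Wnt or primitive streak genes, the median ratio was 1.01 (0.879 to 1.17). The one-to-one rule left out the peaks over the AXIN2 TSS and the highest EVX1 peaks.

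The interval of the ratio excluded 1 at 70 of the 642 peaks, 43 higher and 27 lower in CHIR+SB, where counting error at equal signal would give about 32.1. At 172 promoter peaks the median ratio was 0.874 (0.830 to 0.932) and at 470 other peaks 1.06 (1.02 to 1.099). The quotient of these medians was 0.823 (0.774 to 0.892). Promoter peaks were narrower in CHIR+SB than in CHIR, a median of 0.909 times as wide, and among peaks of similar width the quotient was 0.924 (0.861 to 0.966).

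**Figure D4:**
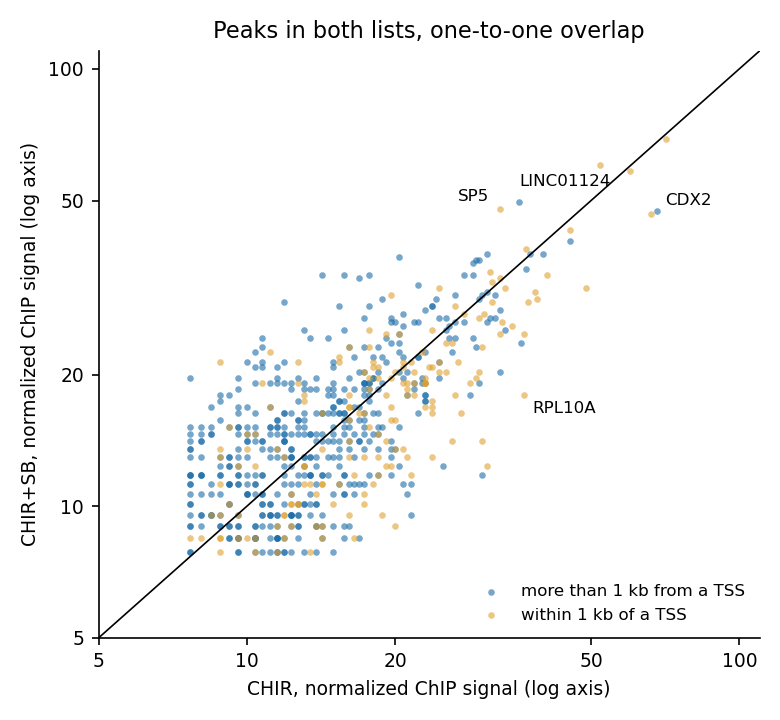
Normalized β-catenin signal of CHIR (horizontal log axis) and CHIR+SB (vertical log axis) at 642 peaks that overlapped one-to-one, 1 point per peak and 1 library per condition, with the line of equal signal. Promoter peaks (within 1 kb of a TSS) are separate from the rest, and the labelled points include CDX2 (68.0 in CHIR, 47.3 in CHIR+SB) and SP5 (32.6 and 47.8).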

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

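Of 286 alternative values, 224 kept their direction and their side of the threshold or stayed within their limits. Some of these 224 could not have changed. A gene list with no member near a peak cannot gain one under a narrower window, a higher minimum or a shorter peak list. In RPMI, the common signal minimum and lists of equal length left the peak list as it was. The count of 224 therefore overstates how robust the results are. No paired analysis was possible because each condition had 1 library, and no replicate could be left out. The common signal minimum, the CHIR minimum applied to CHIR+SB, the comparisons of lists and the members near one list alone above the medians, the Wnt and primitive streak lists without their common members, and all alternatives for signal ratios were chosen after seeing the data. Motif alternatives and random gene lists matched on TSS distance were not run, since no hg19 sequence or annotation was used here, and the Fisher test listed as an alternative became the test reported. Where a minimum or a shorter list changed a value, fewer peaks entered by construction, and for the other changes the cause was not tested. Wnt and primitive streak genes passed the test in CHIR and CHIR+SB under every alternative run. At or above each list's own median there were 135 peaks in RPMI, 550 in CHIR and 995 in CHIR+SB, and at or above the RPMI median 135, 454 and 515. At the common minimum CHIR+SB had 874, and at the CHIR minimum 1807.

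The share of RPMI peaks in the CHIR list was 89.6% among peaks above the medians and 44.6% with 260 top peaks each, and in the CHIR+SB list 86.7% and 36.2%. For CHIR peaks in CHIR+SB it was 78.2% and 69.2%, and 58.9% without peaks found in RPMI. For CHIR+SB peaks in CHIR it was 43.1% and 68.8%, 30.8% without peaks found in RPMI and 55.0% at the common minimum. The share at promoters above the medians was 74.8% in RPMI, 33.5% in CHIR and 20.7% in CHIR+SB. At the common minimum it was 29.8% in CHIR and 22.0% in CHIR+SB, and within 5 kb of the TSS 37.9% and 22.7%.

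With 260 top peaks, the calls of the Nodal, pluripotency, BMP and trophoblast lists in CHIR ended with 1 member each (adjusted p = 0.291, 0.291, 0.277 and 0.277, one-sided Fisher exact test) and that of HOX with 2 (0.151). In CHIR+SB those of the Nodal and BMP lists ended with 1 member each (0.266 and 0.21). Neurectoderm genes reversed to 0 members and an odds ratio under that of other genes in both. Above the CHIR median, neurectoderm ended with 2 members (0.0948) and trophoblast with 1 (0.264), and at the common minimum trophoblast ended with 1 (0.33). In CHIR+SB, BMP targets ended with 2 members within 10 kb (0.0733) and 2 at the common minimum (0.0706), and neurectoderm with 2 there (0.139). Of lists that passed no test, the odds ratio changed sides of 1 with 0 members within 10 kb in RPMI for Wnt, primitive streak and neurectoderm genes. The same held with 0 above the RPMI median for neurectoderm genes and with 0 in RPMI for the Wnt and primitive streak lists without their common members. For genes of differentiated cells it did so in CHIR with 1 member at any distance, 0 above the median and 0 among 260 top peaks. In CHIR+SB it did so with 1 member within 10 kb and 1 without peaks found in RPMI.

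Members near a CHIR+SB peak and no CHIR peak numbered 16, against 13 near a CHIR peak and no CHIR+SB peak. This balance reversed to 8 against 15 within 10 kb, to 8 against 15 at the common minimum and to 3 against 4 with 260 top peaks. Above the medians it was 16 against 4, and within 100 kb 16 against 13. After subtraction of IgG signal, the median ratio of CHIR+SB to CHIR signal was 0.954 over all pairs, 0.819 at promoters, 1.00 at other peaks, 0.983 at peaks absent from RPMI and 0.863 at shared ones. At promoter pairs of similar width it was 0.943. Depth limits peaks near the lowest counts of 15, 20 and 12 reads in RPMI, CHIR and CHIR+SB.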

Other observations

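The gene lists in this paragraph were chosen after the data were seen, as were the tests of the peak number at the CHIR minimum, of chance calls, of binding raised by CHIR and of lower signal at peaks that only CHIR brings. Genes for Wnt receptors and Wnt secretion had 5 of 21 members near a CHIR peak, FZD10, FZD2, FZD7, ROR1 and WLS (one-sided Fisher exact test over 6 added lists, adjusted p = 0.00118), and 4 near a CHIR+SB peak (adjusted p = 0.0139). WLS, needed for Wnt secretion, had a peak 44.1 kb upstream with 35 reads in CHIR and 43 in CHIR+SB, a signal ratio of 1.80 (1.13 to 2.90) over a peak 1.499 times as wide in CHIR+SB. Feedback regulators and targets of FGF/ERK signalling had 4 of 15 members near a CHIR peak, DUSP6, ETV4, ETV5 and SPRY4 (exact test, adjusted p = 0.00167), and 5 in CHIR+SB with DUSP4 added (adjusted p = 0.000473). Hippo pathway genes had 3 of 15 members in CHIR, AMOTL2, ANKRD1 and TEAD1 (exact test, adjusted p = 0.0138), and 6 in CHIR+SB with CCN1, TEAD4 and YAP1 added (adjusted p = 5.98e-05). The difference between conditions was not tested. FZD7, DUSP6 and AMOTL2 are also members of the fixed Wnt or primitive streak lists. Notch genes had 1 of 15 members near a peak in each, HES7 in CHIR (exact test, adjusted p = 0.403) and JAG1 in CHIR+SB (adjusted p = 0.522). The Hedgehog receptor gene PTCH1 was 1 of 13 Hedgehog genes in both (exact test, adjusted p = 0.403 and 0.522), and no retinoic acid gene of 11 was near a peak. In RPMI, FZD2 was the 1 gene of these lists near a peak.

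Several genes had clusters of peaks. AXIN2 had the most peaks in CHIR, 7 over 99.1 kb, followed by MYO3B, which lies on the chromosome of SP5, with 6 over 466 kb. Several of the AXIN2 peaks lay side by side within 1.22 kb of the TSS, so this order depends on how the peaks were split. The MYO3B peak furthest from its TSS, at 502 kb, lay between MYO3B and SP5. FOXB1 had 5 CHIR peaks and 6 CHIR+SB peaks over about 125 kb. ZNF608 had the most in CHIR+SB, 7 over 887 kb.

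The CHIR+SB list was longer than the CHIR list by 1.72 times. Deeper sequencing is argued against as the reason, since the relative depth of the CHIR+SB library over the CHIR library was 0.683. The test of a lower signal minimum set beforehand decided nothing: at the RPMI minimum of 9.61 the ratio was 1.18, between its limits of 1 and 1.5. The gap between the lowest normalized signals of the CHIR and CHIR+SB lists is argued against as the whole reason. Of the 1813 CHIR+SB peaks, 6 lay below the CHIR minimum of 7.68, so without them the ratio, 1.716, could hardly differ from 1.72. Its exact 95% interval on the counts, 1.59 to 1.85, treats peaks as independent counts and holds no spread between libraries. Between 7.68 and 9.61 the CHIR+SB list held 933 peaks and the CHIR list 312. The comparison at 7.68 does not cover a lower minimum in reads, because equal signal took fewer reads in CHIR+SB. The lowest counts were 20 reads in CHIR and 12 in CHIR+SB. In CHIR+SB, 17 reads gave a signal of 9.56 and 18 reads gave 10.1. The 874 CHIR+SB peaks above 9.61 therefore had at least 18 reads. At a common minimum of 20 reads the CHIR+SB list thus held at most 874 peaks, against 1053 in CHIR, and was not longer. Such a limit is stricter in signal for CHIR+SB (11.3) than for CHIR (7.68). A lower minimum in reads stays open as a reason for the longer list. The authors' other thresholds, the deeper IgG library of CHIR+SB and an effect of SB431542 stay open and were not tested.

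In RPMI, without CHIR, the highest peaks lay at promoters such as RBM39 and CDK12. Chance calls of a shallow library are argued against, since 79.7% of RPMI promoter peaks overlapped a peak in both other lists. Background of open promoters could contribute: the median IgG signal at promoter peaks was 1.25 times that at other RPMI peaks, between the 1.5 and 1.1 set beforehand, and it was 1.67 times in CHIR and 1.5 times in CHIR+SB, while IgG signal around the RPMI peaks was 1.03 times. Binding that CHIR raises stays open too, because CHIR signal at promoter peaks in both lists was a median of 1.21 times RPMI signal while the CHIR peaks were also wider. These explanations cannot be told apart with 1 library per condition.

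A lower signal with CHIR+SB at peaks absent from RPMI was looked for, as SB431542 blocks the receptors that activate SMAD2/3, and it was not seen. The median ratio of CHIR+SB to CHIR signal at peaks absent from RPMI, divided by that at shared peaks, was 1.104 (1.02 to 1.21), and 1.07 (0.993 to 1.13) among pairs of similar width. Within promoter peaks it was 0.997 (0.876 to 1.09) and within other peaks 1.01 (0.888 to 1.15), so the overall value went with the share of promoters (63 of 494 absent and 109 of 148 shared peaks), and a modest effect either way stays open. Scaling and peak boundaries were set out to explain a lower signal, and the limit set for scaling wrongly counted a higher one as well, so neither was decided. Only peaks called in both lists entered, so a peak that SB431542 removed, as a candidate explanation for the absence of TBXT from the CHIR+SB list, would not show here.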
